A study of Mus musculus with 8 samples.

How the data were processed

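Splenic naive CD4 T cells of mice labelled C57BL/6J were sorted as CD25 negative, CD44 low and CD62L high at a purity over 98%, per the labels. They were stimulated with antibodies to CD3e and CD28 at 1 ug/ml each and IL-2 at 10 ng/ml, with antibodies to IFN-g and IL-4 at 10 ug/ml each, with or without TGF-b at 2 ng/ml, for 24 h. RNA was taken with Trizol and columns, and 6 ug of total RNA per sample was labelled with biotin for single-colour Affymetrix arrays. There were 8 samples, 1 for each of 4 genotypes with and without TGF-b. The labels do not say that the cultures came from separate animals, so p-values measure the spread between these cultures only. In tests of responses that spread holds real differences between genotypes too.

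The deposited values are probe set intensities on a linear scale, and GCOS 1.4 (Affymetrix GeneChip Operating Software) is named in the submitters' processing notes. Its algorithm, background handling and scaling settings are not given in the sources used here. The deposited medians per array were 39.2 and 27.3 in WT without and with TGF-b, 37.1 and 31.0 in Smad2KO, 28.5 and 31.6 in Smad3KO and 44.4 and 40.9 in Smad2KO_Smad3het, so the table was not at a common level as used here. For arrays, the number of samples limits the precision.

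Each array was scaled to the same 2% trimmed mean, with factors of 0.774 and 1.07 for WT, 0.726 and 0.860 for Smad2KO, 0.917 and 0.840 for Smad3KO and 1.98 and 2.22 for Smad2KO_Smad3het. A floor was set at the median of all scaled signals, 41.8, lower values were set to it, and log2 was taken. A probe set was tested if its highest value was at least 83.7, which is 2 times the floor, and each gene was read from its probe set with the highest mean. The log2 ratio of the 98th percentile of signals to their median was 6.81 to 7.07 on the WT, Smad2KO and Smad3KO arrays and 4.85 and 4.79 on the Smad2KO_Smad3het arrays. The share of probe sets at 2 times the floor or more was 34.2% to 35.7% on the former and 51.4% and 52.3% on the latter. A fold was written as "at least" where the dimmer array was under the floor. When the Smad2KO_Smad3het arrays were left out, scaling, floor (32.5), filter and probe set were chosen again on the other 6, and of 9283 genes tested in both, 8704 kept their probe set and 579 had another.

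Gene names came from the platform annotation given with the series. Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and were left out, and 9160 were unnamed here. The 34945 probe sets covered 18193 symbols. Entrez identifiers matched 34741 probe sets to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was otherwise used only for which genes neighbour each other. The tested probe sets numbered 28827, of which 23624 had 1 symbol, and stood for 13705 genes (9465 on the 6 arrays).

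Responses to TGF-b within a genotype were log2 ratios of 2 arrays, and genes at 2-fold or more with the brighter array at 2 times the floor were counted. The mean response was tested with limma 3.58.1 in R 4.3.3, with genotype as a block, moderated variances with trend and robust settings, and Benjamini-Hochberg adjustment at 0.05. The difference between the WT response and the mean of the mutants, the difference between genotypes with intact and deleted Smad2, and the levels of genotypes with treatment as a block were tested the same way. Residual degrees of freedom were 3 for mean responses and levels and 2 for differences between responses (2 and 1 on the 6 arrays). Genes whose floored values left no residual spread were not tested. Responses were also compared over genes picked in another genotype. List medians were set against 10000 random lists drawn within 20 bins of mean signal. The 16 gene lists covered TGF-b targets, receptors and Smads, Treg, Th1, Th2, Th17, cytotoxic, TCR activation, naive and quiescence, cell cycle, CDK inhibitor and Id, interferon-stimulated, glycolysis and hypoxia, cholesterol synthesis, chemokine and homing receptor, and stress genes. The 8 marker lists covered B, myeloid, CD8 T, NK, gamma-delta T, erythroid, memory T and CD4 T cells. Lists were tested with camera at its preset correlation of 0.01 and with an estimated one, adjusted over all lists and contrasts. Figures were drawn with matplotlib 3.10.9.

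The groups, tests, lists, most alternatives and the naming rule were chosen before the data were examined. The rule named the 10 largest rises and falls in WT and the 5 and 5 in each mutant, up to 10 genes per direction with the smallest p in each test of responses, the 5 largest changes per direction between genotypes among those past the threshold, members of the lists, and always Smad2, Smad3, Smad7, Foxp3, Itgae, Il2, Ifng and Tbx21. A further item of the rule is not reported here. Leaving out both Smad2KO_Smad3het arrays in every result, and further floors, were chosen after seeing the data. The alternatives were quantile normalization, centring of each array on its median log2 (largest shift of a genotype's median TGF-b response 0.06, while levels between genotypes can shift more), floors at the 25th percentile or none (with 8805 values under 1 set to 1), no filter or a filter on the mean, the mean of all probe sets of a gene, limma without trend and robust settings, no genotype block, genes picked at 3-fold, and leaving out each pair or array.

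Each test was tested on simulated data with 100 changed genes per size. For the mean response on 8 arrays (13703 genes), 37% of genes changed by 1 on the log2 scale and 59% of those changed by 2 were called, with 2 unchanged genes called. On 6 arrays (9465 genes) these were 64% and 93%, with 2 unchanged genes called. For WT against the mutants, 14% of differences of 2 and 55% of 4 were called on 8 arrays (13705 genes) and 26% and 68% on 6 (9465 genes), with 1 and 0 unchanged genes called. For Smad2 dependence the shares over the same genes were 11% and 48% on 8 arrays and 28% and 70% on 6, with 0 unchanged genes called in both. For levels between genotypes, again over the same genes, 58% of differences of 2 and 88% of 4 were called on 8 arrays and 90% and 97% on 6, with 4 and 1 unchanged genes called. In 9000 simulated genes with 400 changed and a true retained share of 0.5, the share came out at 0.558 over genes picked independently and 0.524 over genes picked in the first genotype. The simulated genotypes had equal noise and no floor, so this does not check unequal noise or floored signals. A simulated list of 20 genes shifted by 1 had a camera p of 3.3e-57 on 8 arrays and 3.42e-50 on 6, and an unshifted one 0.341 and 0.644. The shifted genes were drawn from those with a residual spread under the median. Noise was independent between genes, so this does not check camera on lists of correlated genes.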

Results

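Gene expression was measured on Affymetrix arrays in mouse CD4 T cells of 4 genotypes, each cultured for 24 h with or without TGF-b at 2 ng/ml. The genotypes were wild type (WT), a conditional Smad2 knockout made in T cells (Smad2KO), a Smad3 knockout (Smad3KO), and Smad2KO cells heterozygous for the Smad3 knockout (Smad2KO_Smad3het). The last genotype was used in place of cells lacking both Smads, since naive cells of that kind were hard to collect. Smad2 and Smad3 are the transcription factors that the TGF-b receptor activates, and the comparisons ask which TGF-b responses need each of them. Each combination of genotype and treatment had 1 array, 8 in all, and the number of arrays limits the precision of every value. Differences between 2 single arrays are given as values, with no replicate check and no p.

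The 2 Smad2KO_Smad3het arrays stood apart from the other 6. Their deposited intensities had 2% trimmed means of 109 and 97.4, against 202 to 298 on the others, and after scaling their median signals were 88.0 and 90.9, against 26.2 to 30.4. Rank correlations across probe sets ran from 0.907 to 0.928 among the other 6 arrays and from 0.659 to 0.693 between these and the Smad2KO_Smad3het arrays. A spiked-in bacterial transcript used as a hybridization control, BioB, had deposited intensities of 758 and 573 on the Smad2KO_Smad3het arrays and 268 to 382 elsewhere, and another, CreX, 11668 and 12619 against 8650.4 to 11158. A probe set for the mouse B1 repeat read 677 and 742 there after scaling and 3670 to 4574 elsewhere. Of the 13705 genes tested, 13253 were bright enough on either of these arrays, against 8187 to 8376 in the other genotypes. Genes that mark other cells were among them. All 9 tested myeloid and 6 tested B cell markers were bright, against 1 of each in every other genotype. The filter fixes these shares in part, since a gene was tested only if bright on at least 1 of the 8 arrays. Nearly all tested genes were bright on these 2 arrays, so the shares are not particular to markers. Csf1r, a receptor of macrophages, read 6146 and 6589 against 14.9 to 30.9 on the others, and Pax5, a B cell transcription factor, 361 and 681 against 3.33 to 24.0. Counts of genes at 2-fold and of limma calls are therefore also given for the other 6 arrays.

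**Figure D1:**
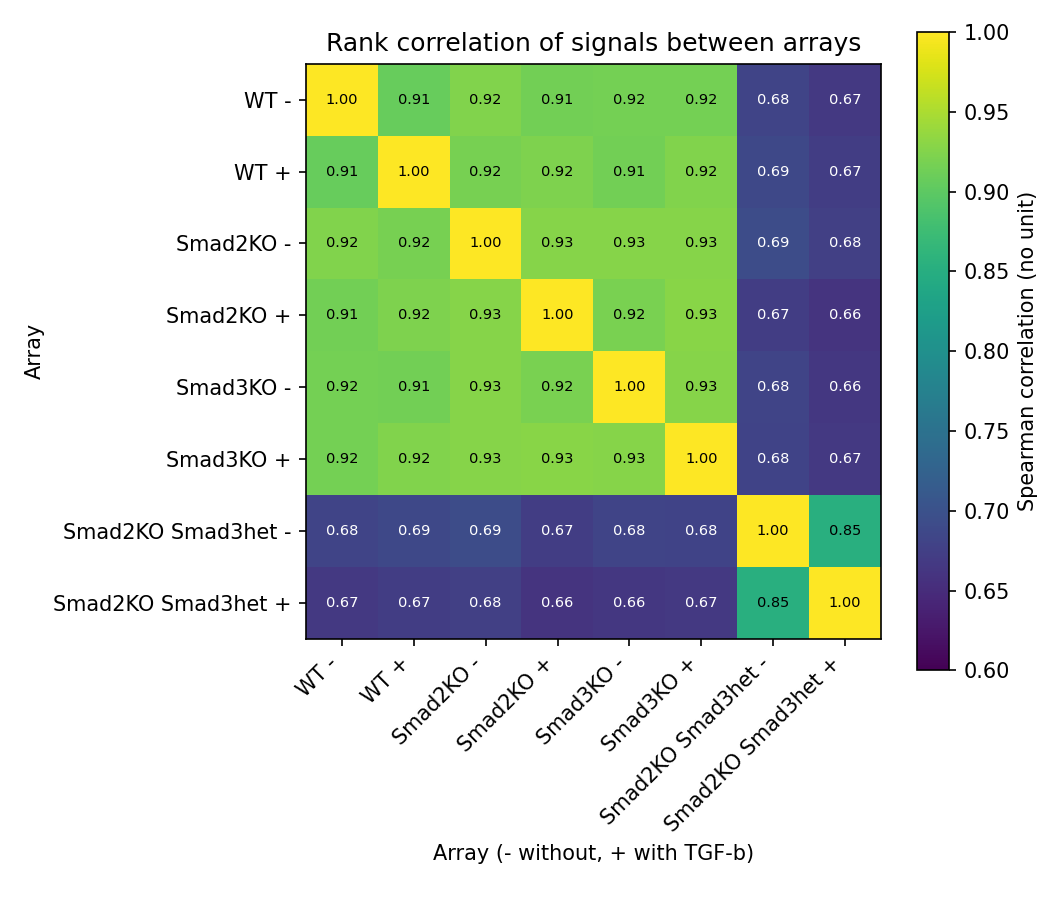
Spearman correlation (no unit) of the signals of all probe sets between each 2 of the 8 arrays, with the arrays on both axes and - or + for culture without or with TGF-b. The 6 WT, Smad2KO and Smad3KO arrays correlate at 0.907 to 0.928 with each other, and the 2 Smad2KO_Smad3het arrays at 0.852 with each other and 0.659 to 0.693 with the rest.

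The targeted genes came first. The Smad2 probe set with the highest mean read 910 and 878 in WT without and with TGF-b, 983 and 891 in Smad2KO, 846 and 817 in Smad3KO and 648 and 596 in Smad2KO_Smad3het, so it was not lower in Smad2KO than in WT. The Smad3 probe set with the highest mean read 127 and 467 in WT, 153 and 372 in Smad2KO, 523 and 622 in Smad3KO and 151 and 352 in Smad2KO_Smad3het, so without TGF-b it was higher in Smad3KO than in WT. Another Smad3 probe set read 64.2 and 143 in WT and 244 and 169 in Smad3KO. A further probe set read 21.3 and 88.0 in WT and 36.8 and 41.5 in Smad3KO, where both signals lay under the floor. A probe outside the deleted part of a gene checks nothing, and where these probes lie relative to the deletions is not given in the sources used here, so these values do not check the labels. With TGF-b, Smad3 was 1.88 higher on the log2 scale in WT, 1.29 in Smad2KO, 1.22 in Smad2KO_Smad3het and 0.25 in Smad3KO.

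In WT cells TGF-b culture went with much higher signals of Maf, a transcription factor of helper T cell cytokine genes, of the chemokine receptor Ccr8 and of Ctsw, a protease of cytotoxic lymphocytes. Maf was at least 53.7-fold higher, Ccr8 at least 48.5-fold, and Ctsw 43.6-fold, from 63.8 to 2784. The other 7 of the 10 largest rises were Adam19 at least 28.9-fold, Socs2, an inhibitor of cytokine signalling, 27.2-fold, Ctla2a at least 24.0-fold, Aqp3, a water and glycerol channel, 22.7-fold, Nt5e, an ecto-enzyme that makes adenosine, 21.0-fold, Emp1 at least 20.8-fold and Kctd14 20.7-fold. The 10 largest falls were led by Nrn1, 13.8-fold lower with TGF-b (2699 to 195), and Il2, the T cell growth factor, 9.40-fold lower (4315 to 459). Serpinb6b was 7.21-fold lower, AI504432 6.84-fold, Ifitm2 5.92-fold, the potassium channel gene Kcna3 5.87-fold, Ms4a4c 5.52-fold, Ifi209 5.18-fold, Lypd6b at least 5.0-fold and Ifih1, a sensor of viral RNA, 4.96-fold. Foxp3, the transcription factor of regulatory T cells, read 2.36 without and 342 with TGF-b. Ranks of rises and falls are by floored signals, so genes with a signal under the floor have bounds and no true order. Foxp3 was thus not among the rises, nor Gzmb (96.8 to 1.03) and Eomes (119 to 3.21) among the falls. In all, 326 genes were at least 2-fold higher and 181 at least 2-fold lower, together 6.05% of the 8376 genes bright enough on either WT array. Prepared without the Smad2KO_Smad3het arrays, the counts were 420 and 268. The 3 probe sets for 18S ribosomal RNA read 3424, 2680.2 and 2226 on the WT array without TGF-b and 156, 60.2 and 104 on the WT array with it.

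**Figure D2:**
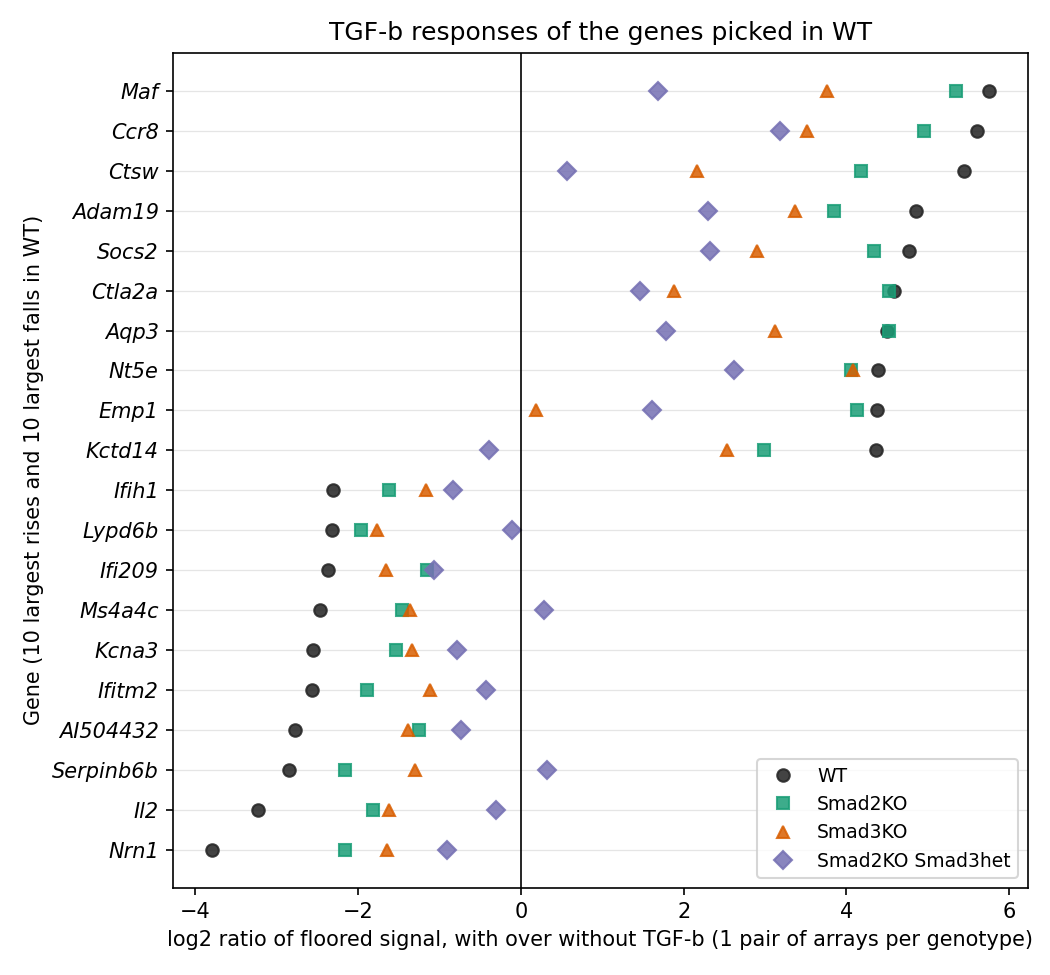
Log2 ratio of floored signal with over without TGF-b (x axis) in each genotype for the 10 largest rises and 10 largest falls in WT (y axis), each point 1 pair of arrays. Maf is at 5.75 in WT, 5.34 in Smad2KO and 3.76 in Smad3KO, Emp1 at 4.38, 4.13 and 0.19 (lower bounds, since their signals without TGF-b lay under the floor), and Nrn1 at -3.79, -2.16 and -1.65.

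Of the 507 genes at 2-fold in WT, 252 were at 2-fold in the same direction in Smad2KO. Maf was at least 40.6-fold higher with TGF-b, Ccr8 at least 31.0-fold, Ctla2a at least 23-fold, Aqp3 at least 22.9-fold and Socs2 20.3-fold, and Foxp3 went from 21.0 to 245. Among the falls, E2f5, a regulator of cell cycle genes, was at least 5.51-fold lower, while its log2 ratios were 0.59 in WT and 0.15 in Smad3KO. This probe set was chosen for its signals of 10992 and 12144 on the Smad2KO_Smad3het arrays, and the other 2 for E2f5 stood at -0.35 and -0.43 in Smad2KO and -0.64 and -0.38 in WT. Serpinb9, an inhibitor of granzyme B, had log2 ratios of -1.99 in WT, -2.35 in Smad2KO and -1.78 in Smad3KO, and Ces5a -2.19 or lower, -2.33 or lower and 0.83. The Ces5a probe set read 1333 and 1977 on the Smad2KO_Smad3het arrays. Other probe sets for Ces5a lay under the floor on the WT, Smad2KO and Smad3KO arrays, so its ratios rest on this probe set alone. Nrn1 and Serpinb6b, at -2.16 each, completed the 5 largest falls. Il2 was 3.53-fold lower in Smad2KO, from 4716 to 1337. There were 210 genes at least 2-fold higher and 114 at least 2-fold lower, 3.92% of 8266 bright genes, and 267 and 159 on the 6 arrays.

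In Smad3KO several of these genes had smaller ratios. Maf was at least 13.5-fold higher, reaching 566 with TGF-b against 2246 in WT and 1697 in Smad2KO, Ccr8 at least 11.5-fold and Adam19 at least 10.3-fold, whereas Nt5e, at least 16.9-fold higher, lay beside the at least 16.6-fold of Smad2KO. Ccr6, a chemokine receptor of helper T cells, was at least 3.51 higher on the log2 scale of floored signals, against 3.41 in WT and 2.73 in Smad2KO. Foxp3 went from 17.6 to 85.3, and Il2 was 3.08-fold lower, from 4538 to 1472. The 5 largest falls included the cytotoxic effector gene Gzmb, at least 4.20-fold lower, Eomes, a transcription factor of cytotoxic cells, at least 3.81-fold lower, and Clec2i, at least 3.38-fold lower, with Serpinb9 and Lypd6b. There were 127 genes at least 2-fold higher and 56 at least 2-fold lower, 2.24% of 8187 bright genes, and 170 and 75 on the 6 arrays. With a floor at the 25th percentile the counts were 711 and 593, against 668 and 849 in Smad2KO. Over genes bright on both arrays of a pair, the robust SD of log2 ratios was 0.315 in WT and 0.249 in Smad2KO. It was 0.187 in Smad3KO and 0.433 in Smad2KO_Smad3het, the same order as the counts at 2-fold. A wider spread in a pair can by itself give more genes at 2-fold, so the counts alone do not compare the genotypes.

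In Smad2KO_Smad3het, 1515 genes were at least 2-fold higher with TGF-b and 1275 at least 2-fold lower, 21.1% of 13253 bright genes. The largest were Itgb5, an integrin subunit, 16.0-fold higher, Herc6 15.3-fold, Tmem151a 15.1-fold, H2-Ea 14.3-fold and Fam98c at least 14.0-fold. The largest falls were Rpl41, a ribosomal protein gene, 22.7-fold lower, Pgap6 at least 20.2-fold, A830082K12Rik at least 16.1-fold, the tight junction gene Cldn3 15.5-fold and Rab6b 14.3-fold. Itgb5 had log2 ratios of -0.84, -0.39 and -0.81 in WT, Smad2KO and Smad3KO, and Rpl41 of 0.42, 0.15 and -0.10. Of these 10 genes 8 had other probe sets, and for 6 of the 8, Herc6, H2-Ea, Rpl41, A830082K12Rik, Cldn3 and Rab6b, none of those was 2-fold in the same direction. Median signals of these 2 arrays, 88.0 and 90.9, lay above the floor of 41.8, and the dimmer signals of Tmem151a (65.3), Fam98c, Pgap6 and A830082K12Rik lay under them. Among the leading WT genes, Socs2 was 5.01-fold higher in this genotype, from 202 to 1012, and Il2 1.23-fold lower. Ccr8 read 58.7 and 532 and Nt5e 48.1 and 295, where the signals without TGF-b lay under the median of that array, and 2 other Nt5e probe sets stood at 0.13 and at least 1.20 on the log2 scale. Across the 13705 genes tested, log2 responses in this genotype correlated with those of WT, Smad2KO and Smad3KO at Pearson 0.124, 0.127 and 0.113, against 0.743 between WT and Smad2KO, 0.618 between WT and Smad3KO and 0.60 between Smad2KO and Smad3KO. Many genes passed the filter only through the Smad2KO_Smad3het arrays and had floored responses at or near 0 in the other genotypes. The low coefficients of this genotype are thus partly set by the filter. Genes are not independent replicates, so these 6 coefficients describe the arrays.

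The mean TGF-b response over genotypes could be tested, with each genotype as a block and responses compared with their spread between genotypes. Real differences between genotypes enlarge that spread, so a large response of unequal size can fail. Il2, with log2 ratios of -3.23 in WT, -1.82 in Smad2KO and -1.62 in Smad3KO, is such a case below. On the 6 WT, Smad2KO and Smad3KO arrays, Nt5e rose by 4.38 on the log2 scale (SE 0.137, limma adjusted p = 1.05e-08), Vim, an intermediate filament gene, by 2.48 (SE 0.0908, adjusted p = 3.78e-08), Pmepa1, a feedback inhibitor of TGF-b signalling, by 2.84 (SE 0.133, adjusted p = 8.14e-07) and Ccr6 by 3.25 (SE 0.180, adjusted p = 9.15e-07). The other 6 of the 10 rises with the smallest p were Cish at 1.72, Pdgfb at 1.98, Cpd at 1.85, Hemk1 at 2.26, Dusp4 at 1.67 and Plp2 at 1.25. The falls with the smallest p were Dusp6, a phosphatase acting on ERK, at -1.25 (SE 0.0798, adjusted p = 2.09e-06) and Stat4, a transcription factor of the IL-12 response, at -1.5 (SE 0.111, adjusted p = 7.26e-06), followed by Serpinb9 at -2.04, Afp at -1.08, Snx9 at -1.53, Pou2af1 at -1.01, Mndal at -1.09, Slco4a1 at -1.85, Eea1 at -0.89 and Slamf6 at -1.83. In all, 677 of 9465 genes rose and 534 fell. Smad7, the inhibitory Smad, rose by 1.14 (SE 0.150, adjusted p = 0.000476) and Foxp3 by at least 2.80 (SE 0.363, adjusted p = 0.00215). Maf rose by at least 5.55 (SE 0.459, adjusted p = 0.00827). These are means of floored signals, and "at least" or "or lower" marks those where a dimmer signal lay under the floor of 32.5. Il2 had a mean log2 response of -2.23 that did not pass (SE 0.463, adjusted p = 0.124), and neither did Nrn1 at -2.53 (adjusted p = 0.158), Ctsw at 4.13 or more (adjusted p = 0.087), Emp1 at 3.37 or more (adjusted p = 0.247), Ifng at -0.64 (adjusted p = 0.093) or Tbx21, a Th1 transcription factor, at -0.16 (adjusted p = 0.753), where both Smad2KO signals lay under the floor.

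On all 8 arrays, which added the Smad2KO_Smad3het pair, 15 of 13705 genes rose and 4 fell, all 19 among the 1211 called on the 6 arrays. With every array centred on its median log2 the split was 21 and 11. The counts were 70 and 28 with quantile normalization, 58 to 173 and 22 to 85 with other floors or a filter on mean signal, 8 and 3 with the mean of probe sets, 5 and 0 without the genotype block, 1 and 0 with no filter, and 0 and 0 without limma's trend and robust settings. Cish, an inhibitor of cytokine receptor signalling, rose by 1.67 (SE 0.0641, adjusted p = 0.0156), Igfbp4 by 2.17 (SE 0.110, adjusted p = 0.0216), Dusp4 by 1.59 (SE 0.0898, adjusted p = 0.0282), Skil, a repressor of Smad-driven transcription, by 1.81 (SE 0.115, adjusted p = 0.0332) and Capg by 2.26 (SE 0.158, adjusted p = 0.0332). Med14 at 0.98, Ltb at 0.75, Mical1 at 1.46, Itgb2 at 0.89 and Mllt6 at 1.12 completed the 10 with the smallest p. The 4 falls were Itm2a at -0.56, Eea1 at -0.86, Sptlc1 at -0.71 and Tmem126a at -0.57. Leaving out the WT pair left 1 rise and 0 falls, and leaving out the Smad2KO or the Smad3KO pair left 0 of each. At an unadjusted p under 0.05 limma counted 1883 genes on 8 arrays and 2663 on 6.

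Gene lists fixed beforehand were read on the 6 arrays, over the members also tested on the 8, and no called member changed sign under quantile normalization or centring. With quantile normalization the calls were 6 higher in place of 7 for Treg genes, 3 lower in place of 4 for Th1 genes, 4 lower in place of 5 for cell cycle genes and 1 higher in place of 2 for interferon-stimulated genes. With centred arrays they were 8 lower in place of 7 for TCR activation genes and 0 higher in place of 1 for cholesterol synthesis genes. The other counts of calls were the same. Of 16 tested TGF-b targets, 12 rose and 0 fell, 13 and 1 adjusted over the list alone. Besides Smad7, Foxp3, Pmepa1 and Ccr8 these were Skil at 1.84, Ski at 1.28, Klf10 at 1.93, Spsb1 at 1.91, Ldlrad4 at 1.70 or more, Id2 at 0.89, Smurf2 at 0.52 and Tgfb1 at 0.39. Id3 was at -0.81 (adjusted p = 0.142) and passed only over the list alone (adjusted p = 0.0399). Of 13 TGF-b receptors and Smads, 6 rose and 0 fell (7 and 0 adjusted over the list alone), namely Tgfbr1 by 2.79, Bmpr2 by 1.70, Acvr2a by 1.56, Acvr1b by 0.92, Tgfbr2 by 0.68 and Tgfbr3 by 0.53. The Itgae probe set, for an integrin subunit that TGF-b is known to induce in T cells, read below the floor of 41.8 on these 6 arrays.

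Genes of several helper T cell programmes rose with TGF-b in the same cultures, which held antibodies to IFN-g and IL-4. Of 17 Treg genes 7 rose and 1 fell, with the same counts adjusted over the list alone. Beside Foxp3, Nt5e and Socs2 (4.0) rose Capg by 2.41, Ikzf4 by 1.86, Gpr83 by 1.27 and the IL-2 receptor chain Il2ra by 0.95, and Ebi3 was at -1.15 or lower. Of 9 Th17 genes 6 rose and 1 fell (8 and 1 adjusted over the list alone). Maf, Ccr6, Ahr by 2.69, Rora by 2.26, Il6ra by 1.34 and Stat3 by 0.39 rose, and Batf fell by 0.33. Of 7 Th2 genes 4 rose and 0 fell (5 and 0 adjusted over the list alone), and these were Maf, Ccr8, Ccr4 by 1.25 and Irf4 by 0.40, while Gata3, the Th2 master regulator, was at 0.37 (adjusted p = 0.163). Of 14 Th1 genes 3 rose and 4 fell (4 and 5 adjusted over the list alone). Eomes was at -2.41 or lower, Stat4 fell by 1.5, the IL-12 receptor chain Il12rb1 by 0.74 and the chemokine gene Ccl4 by 0.73, and Lta rose by 1.85, Il18r1 by at least 1.83 and Xcl1 by 1.18. Of 8 cytotoxic genes 1 rose and 5 fell (2 and 5 adjusted over the list alone), with Gzmb at -2.35 or lower, Serpinb9 at -2.04, Crtam at -1.39 and Fasl at -0.56 beside Eomes, and Nkg7 rising by 1.52.

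Genes of naive and resting T cells rose too. Of 17 tested, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Klf2, a transcription factor of quiescent T cells, up by 1.85, its target S1pr1, a receptor for exit from lymph nodes, by 1.16, Foxo1 by 1.09, Pik3ip1 by at least 0.97, the IL-7 receptor Il7r by 0.93, Ets1 by 0.50, Btg1 by 0.47 and Ccr7 by 0.45, and Satb1 down at -0.33. Of 16 chemokine and homing receptors 8 rose and 0 fell (11 and 1 adjusted over the list alone), among them Ccr6, Ccr8, Ccr4, Selplg by 1.17, Itga6 by 0.68 and Itgb7 by 0.63. Of 24 TCR activation genes 5 rose and 7 fell (7 and 9 adjusted over the list alone). Il3 fell by 1.16, Cd40lg by 0.86, Egr1 by 0.77, Cd69 by 0.70, Nr4a2 by 0.62, Egr3 by 0.56 and Myc by 0.23, and Irf8 rose by 2.64, Nr4a3 by 0.84, Icos by 0.35, and Il2ra and Irf4 as above. Of 29 cell cycle genes 0 rose and 5 fell, also adjusted over the list alone. These were Aurkb at -0.63, Bub1 at -0.46, Cdk1 at -0.38, Birc5 at -0.37 and Ccna2 at -0.29. Mki67 was at -0.09 (adjusted p = 0.467). Of 8 CDK inhibitors and Id genes 3 rose and 0 fell, also adjusted over the list alone, namely Id1 by 1.76, Id2, and Cdkn1b, an inhibitor of cell cycle kinases, by 0.76.

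Of 17 glycolysis and hypoxia genes 1 rose and 4 fell (1 and 6 adjusted over the list alone): Hk2 fell by 0.50, Slc2a3 by 0.39, Slc2a1 by 0.32 and Pfkl by 0.30, all acting in glucose uptake or glycolysis, and Egln3 rose by 2.47. Of 16 cholesterol synthesis genes 1 rose and 3 fell, also adjusted over the list alone, with Lss at -0.68, Msmo1 at -0.31 and Hmgcs1 at -0.29 against Sc5d at 0.26, which did not pass with centred arrays. Of 13 interferon-stimulated genes 2 rose and 2 fell (3 and 2 adjusted over the list alone), Ifit3 by at least 1.03 and Igtp by 0.78 up and Ifih1 at -1.70 and Gbp2 at -0.74 down. Of 16 stress and immediate early genes 2 rose and 3 fell (3 and 3 adjusted over the list alone), with Ier3 up by at least 1.20 and Jun by 0.66, and Fos at -1.19, Zfp36 at -0.32 and Hsph1 at -0.27 down.

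Markers of other cells were followed beside these groups. Of 6 memory T cell markers 2 rose and 0 fell (5 and 0 adjusted over the list alone), Il2rb by 1.42 and Ahnak by 1.37. Of 7 CD4 T cell markers 0 rose and 1 fell, also adjusted over the list alone, Zap70 at -0.27, and Cd4 itself was at -0.03 (adjusted p = 0.872). The single B cell marker tested on the 6 arrays, Cd74, fell by 0.49 (adjusted p = 0.0455), and 0 of 2 myeloid and 0 of 2 CD8 T cell markers were called by limma. NK cell and gamma-delta T cell markers were tested only with the Smad2KO_Smad3het arrays, 4 and 2 of them, where 0 were called, and 0 erythroid markers were bright enough. Across the 16 lists and 8 marker lists on all 8 arrays, limma called 1 TGF-b target, Skil, and 2 Treg genes, Capg and Nt5e.

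The median response of each list was also set against 10000 random lists of the same size, read in the same pair of arrays. They were matched on mean signal over the 8 arrays, not on brightness within the pair. Genes under the floor on both arrays of a pair count as 0, which draws medians toward 0 in lists and random lists. It need not do so equally: in WT 16 of 17 TGF-b targets were bright, against 8376 of the 13705 tested genes. The percentiles may thus partly reflect how many members of a list were bright. TGF-b targets had median log2 responses of 0.98 in WT, 1.17 in Smad2KO and 0.57 in Smad3KO, above all random lists in each, and 0.43 in Smad2KO_Smad3het, at percentile 99.8. Chemokine and homing receptors had medians of 0.80, 0.49 and 0.22 in WT, Smad2KO and Smad3KO, Th17 genes 0.80, 0.40 and 0.43, Th2 genes 0.73, 0.45 and 0.49 and naive and quiescence genes 0.48, 0.33 and 0.29. Cytotoxic genes were at -0.35, -0.45 and -0.05, cell cycle genes at -0.14, -0.24 and -0.03, and glycolysis and hypoxia genes at -0.27, -0.12 and -0.11. In Smad3KO cytotoxic genes lay at percentile 7.92 and cell cycle genes at 43.7, so neither stood clear of the random lists. Of 10 cytotoxic genes 8 were bright in each genotype. At 2-fold, 2 rose and 4 fell in WT and Smad2KO, and 2 and 3 in Smad3KO. Their mean responses were 0.02, -0.30 and -0.30, so the median of -0.05 does not show that the falls were lost. Treg genes were at 0.28, 0.32 and 0.04, where the last was -0.02 with centred arrays. Receptors and Smads, with 11 of 18 bright in WT, were at 0.03 there, which was -0.00 with centred arrays. TCR activation genes were at -0.21, -0.09 and 0.06, where the last was -0.00 with centred arrays. With quantile normalization, which changed the members tested in some lists, cytotoxic genes were at -1.15, -1.09 and -0.53, Treg genes at 0.46, 0.56 and 0.26, Th2 genes at 0.85, 1.00 and 0.46, with Smad2KO then above WT, and receptors and Smads at 0.27 in WT.

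**Figure D3:**
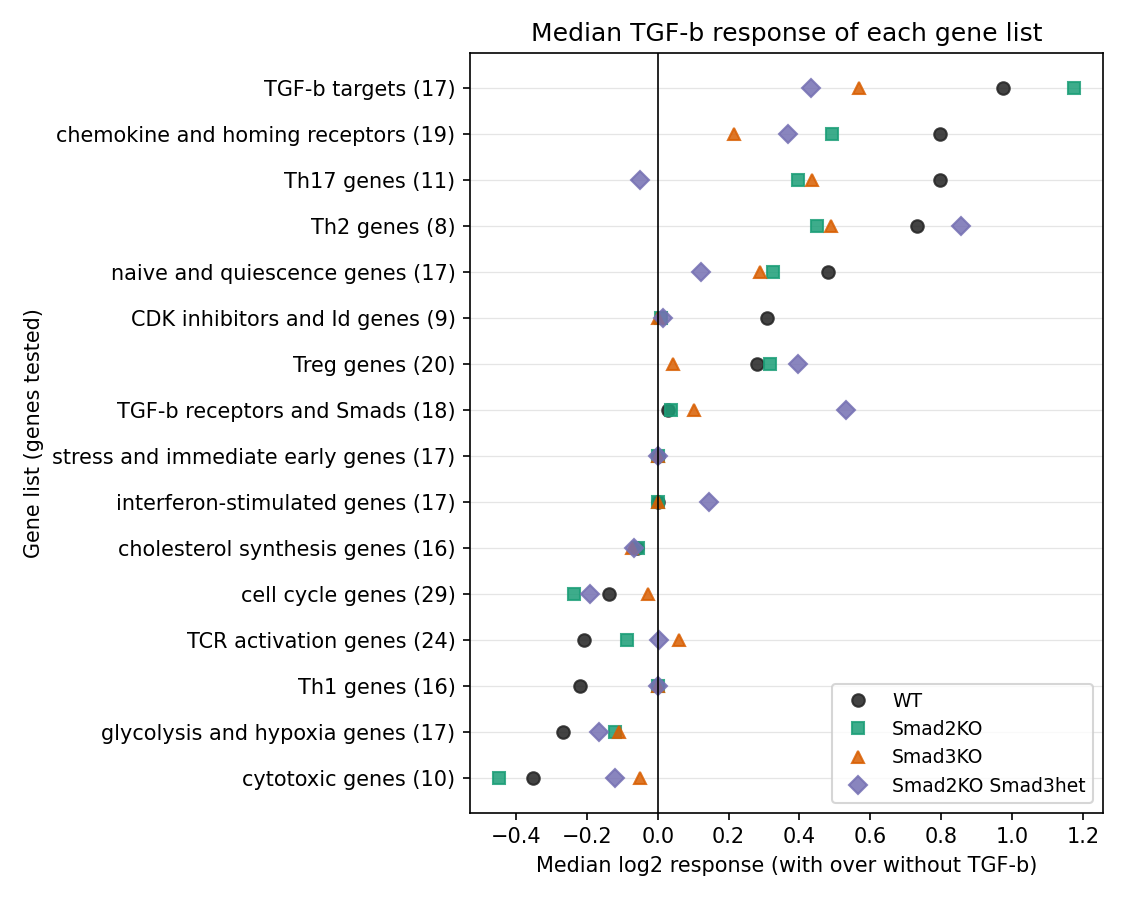
Median log2 response to TGF-b (x axis, with over without) of the tested members of each of 16 gene lists (y axis, number of genes in parentheses), each point 1 genotype with 1 pair of arrays. Members under the floor on both arrays of a pair count as 0. TGF-b targets are at 0.98 in WT, 1.17 in Smad2KO, 0.57 in Smad3KO and 0.43 in Smad2KO_Smad3het, and cytotoxic genes at -0.35, -0.45, -0.05 and -0.12; with centred arrays or quantile normalization some medians within 0.06 of 0 change sign, and with quantile normalization cytotoxic genes are at -1.15, -1.09, -0.53 and -0.24.

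Camera, which asks whether a list moved more than other genes, called 10 lists for the mean response on 8 arrays and 9 on 6 with its preset correlation. TGF-b targets moved up with an adjusted p of 2.37e-08 on the 6 arrays, chemokine and homing receptors with 6.05e-07, Th17 genes with 1.7e-06, Th2 genes with 1.44e-05, naive and quiescence genes with 2.61e-05, Treg genes with 0.000275, memory T cell markers with 0.000319 and receptors and Smads with 0.000372. Cell cycle genes moved down (adjusted p = 0.0194), and glycolysis and hypoxia genes were called on 8 arrays only (adjusted p = 0.0163, against 0.151 on 6). None of these calls held with an estimated correlation, where the smallest adjusted p was 0.551 on 8 arrays and 0.761 on 6.

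Which responses kept their size without Smad2 or Smad3 was asked of genes picked in 1 genotype and measured in the others. Over the 507 genes picked in WT, the median response in the direction of the pick was 1.37 on the log2 scale in WT, 1.00 in Smad2KO, 0.658 in Smad3KO and 0.367 in Smad2KO_Smad3het. Genes picked for size regress in any other pair, so WT was compared with each knockout over genes picked in the remaining one. Over the 183 genes picked in Smad3KO, the median was 1.58 in WT (95% interval 1.37 to 1.78) and 1.29 in Smad2KO (1.13 to 1.44), with WT larger for 138 genes and Smad2KO for 45. Over the 324 genes picked in Smad2KO, it was 1.48 in WT (1.33 to 1.57) and 0.785 in Smad3KO (0.673 to 0.873), with WT larger for 282 and Smad3KO for 39. Over the WT picks the response was larger in Smad2KO for 369 genes and in Smad3KO for 136. On the 6 arrays the medians were 1.42 in WT and 1.15 in Smad2KO over Smad3KO picks, 1.38 in WT and 0.734 in Smad3KO over Smad2KO picks, and 0.892 in Smad2KO and 0.599 in Smad3KO over WT picks. With a floor at the 25th percentile they were 0.182 and 0.123, 0.423 and 0.177, and 0.196 and 0.0944. The median differences were 0.341, 0.677 and 0.294 in the 3 cases, and the intervals cover the spread between genes, which are not independent replicates, of 1 pair of cultures per genotype.

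**Figure D4:**
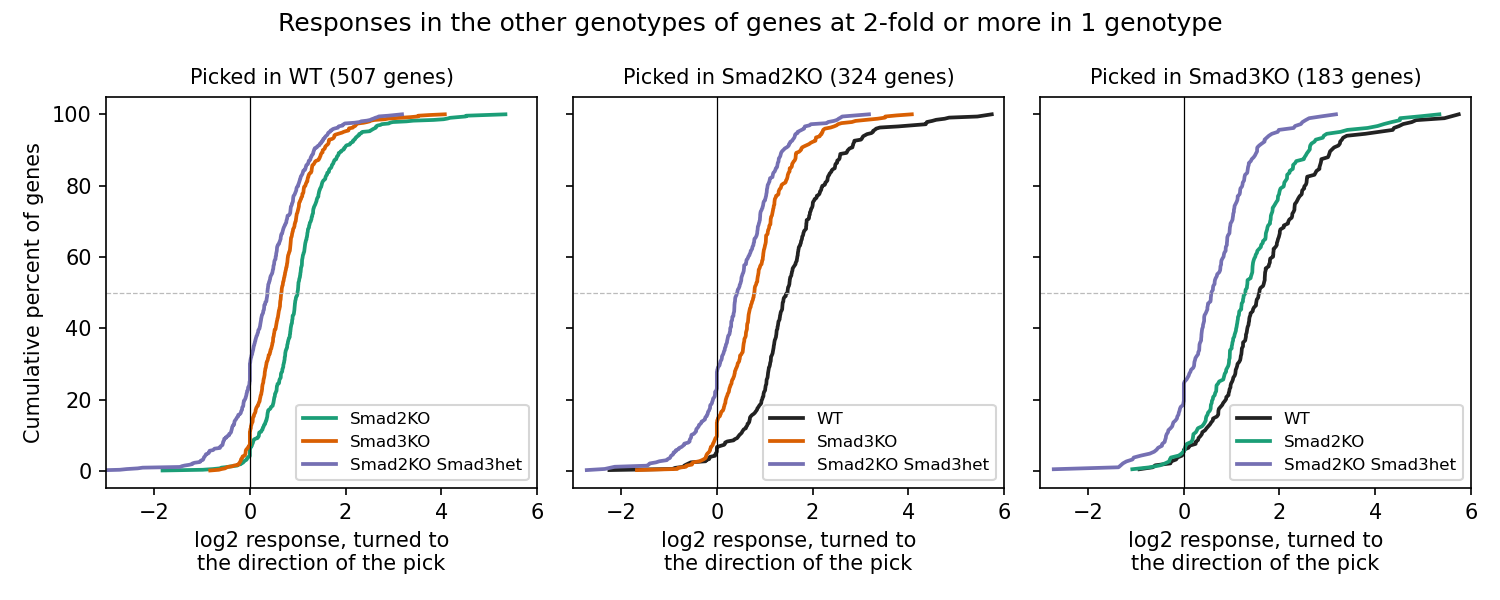
Cumulative percent of genes (y axis) against their log2 response to TGF-b turned to the direction of the pick (x axis), for genes at 2-fold or more in WT (507 genes), Smad2KO (324) or Smad3KO (183), each line another genotype with 1 pair of arrays. For the genes picked in Smad2KO the median is 1.48 in WT and 0.785 in Smad3KO, and for those picked in Smad3KO it is 1.58 in WT and 1.29 in Smad2KO.

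Gene by gene, 79 genes were at least 2-fold higher in WT, Smad2KO and Smad3KO alike and 34 at least 2-fold lower. A further 50 were at least 2-fold higher in WT and Smad2KO but under 1.5-fold in Smad3KO, and 19 likewise lower, by floored signals. Both Smad3KO signals were at the floor or above for 35 of the 50 and for all 19, while 7 of the 50, Emp1 and Il18r1 among them, had 1 and 8 had both under it, so their Smad3KO ratios are not settled. Beside Smad3, the 35 held Gpr83, with log2 ratios of 1.76, 1.60 and 0.47 in WT, Smad2KO and Smad3KO, and the activin receptor Acvr1b with 1.17, 1.28 and 0.31. Smad3 itself is the targeted gene in Smad3KO, where it read 523 and 622, so its small ratio there need not show a lost response. The reverse class, 2-fold higher in WT and Smad3KO but under 1.5-fold in Smad2KO, held 8 genes, and 2 were likewise lower, with both Smad2KO signals at the floor or above for 6 and 1 of them. Among the 6 the chemokine gene Xcl1 had ratios of 1.8, 0.46 and 1.30. Prepared on the 6 arrays, these classes held 93 and 41, 59 and 23, and 8 and 1 genes, higher and lower. Each ratio rests on 1 pair of arrays. Limma's test of Smad2 dependence on the 6 arrays put Xcl1 at 1.09 (adjusted p = 0.304). It put 1600014C10Rik, also among the 6 genes, at 1.34 (adjusted p = 0.0548). No gene of these classes passed a test of the difference in response on the 8 or the 6 arrays, and Smad3KO against the others was not tested. For the 50 and 19 genes this was nearly fixed by the picking. On the 6 arrays the spread came from Smad2KO against Smad3KO in 1 test and from WT against Smad3KO in the other. The genes were picked by these differences, so their failure says nothing about a need for Smad3.

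Tests of the difference in response itself called almost no gene. Between WT and the mean of the mutants limma called 0 of 13704 genes on 8 arrays (304 at an unadjusted p under 0.05, smallest adjusted p = 0.991) and 1 of 9438 on 6, AY036118, at 3.13 (SE 0.198, adjusted p = 0.0129), with 700 at an unadjusted p under 0.05. Between genotypes with and without intact Smad2 it called 0 of 13705 on 8 arrays (154 at an unadjusted p under 0.05, smallest adjusted p = 0.871) and 1 of 9463 on 6, Tatdn2, at 1.68 (SE 0.274, adjusted p = 0.000796), with 216 at an unadjusted p under 0.05. Without the Smad3KO pair the former test gave 2 higher and 3 lower. The latter gave 2 higher without the WT pair, 2 higher and 3 lower without the Smad3KO pair, and 478 higher and 398 lower without the Smad2KO pair, where Smad2KO_Smad3het alone stood for the loss of Smad2. By camera with the preset correlation, chemokine and homing receptors (adjusted p = 1.39e-05) and memory T cell markers (adjusted p = 0.000816) responded more in WT than in the mutants, as did naive and quiescence genes, Th17 genes and Th2 genes on 8 arrays (adjusted p = 0.00705, 0.015 and 0.026). The first 2 lists were called on 6 arrays too (adjusted p = 0.000974 and 0.0351), and none held with an estimated correlation, the smallest adjusted p then being 0.551 on 8 arrays and 0.761 on 6. Here too that setting was weaker by itself. Memory T cell markers, with an estimated correlation of -0.067 on 6 arrays, went from a camera p of 0.008 to 0.224. For Smad2, up means a higher response in genotypes with intact Smad2 than in those without, and down a lower one. On 8 arrays Th17 genes (adjusted p = 0.00911) and memory markers (adjusted p = 0.015) were up. Interferon-stimulated genes (adjusted p = 0.0425) and myeloid markers (adjusted p = 0.0388) were down. On 6 arrays cytotoxic genes (adjusted p = 0.0448) and cell cycle genes (adjusted p = 0.0339) were up and interferon-stimulated genes down (adjusted p = 0.00494). Called members of the cytotoxic and cell cycle lists mostly fell in the mean response, so up there means a smaller fall with intact Smad2. Again no list held with an estimated correlation, at the same smallest adjusted p of 0.551 and 0.761, which has the same limit.

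Levels were also compared between genotypes over both treatments. On the 6 arrays Smad2KO differed from WT in 49 genes higher and 47 lower. The ubiquitin ligase gene Mid1 was 2.28 higher on the log2 scale (limma adjusted p = 1.7e-07), Rbm45 2.68 (adjusted p = 2.33e-06), Fads6 at least 1.58 (adjusted p = 0.0333), Cap1, which acts on actin, 1.41 (adjusted p = 3.06e-06) and Ap1s3 1.35 (adjusted p = 0.0227). AI506816 was at -5.36 or lower (adjusted p = 2.33e-09), with signals of 14.5 and 3.19 in Smad2KO, 1510.4 and 1187 in WT and 667 and 573 in Smad3KO. Gdpd3 was at -3.89 or lower, Ccnb1ip1 at -3.60 or lower, Npl at -2.38 or lower and Mau2, a cohesin loader, at -2.10. The floor of 32.5 sets the first 4 values, since both Smad2KO signals lay under it, so they are bounds with no order. On 8 arrays the call was 1 higher, Mid1 at 2.28 (SE 0.0802, adjusted p = 0.00422), and 1 lower, AI506816 at -4.77 or lower (SE 0.122, adjusted p = 0.00193), with 425 genes at an unadjusted p under 0.05, and other settings gave up to 6 higher and 7 lower. These counts were 6 and 10 or 8 and 13 without either Smad2KO_Smad3het array. They were 0 and 0 without either WT array, and 0 and 1 without any one of the other 4.

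In Smad3KO, Ifng, the Th1 cytokine gene, was 2.21 higher than in WT on the 6 arrays (SE 0.281, limma adjusted p = 0.00526), with scaled signals of 271 and 180.0 against 65.3 and 35.1. The interferon-induced GTPase genes Gbp2b at 2.19 (adjusted p = 1.74e-05) and Gbp6 at 1.39 (adjusted p = 0.0489), Tmem87a at 1.20 and Fbxo17 at 1.06 were the other large rises. The potassium channel gene Kcnj11 was at -2.93 (adjusted p = 8.71e-08), the glutamine transporter gene Slc1a5 at -1.81 (adjusted p = 1.21e-06), the inflammatory caspase gene Casp4 at -1.58 or lower (adjusted p = 0.00402), Rpgrip1 at -1.40 and Atm, the DNA damage kinase gene, at -1.35 (adjusted p = 0.000932). In all 21 genes were higher and 23 lower. On 8 arrays limma called 0 higher and 1 lower, Slc1a5 at -1.81 (SE 0.0853, adjusted p = 0.045), with 476 genes at an unadjusted p under 0.05. Limma called 0 lower with centred arrays, with no filter or without limma's trend and robust settings. Without either Smad2KO_Smad3het array the counts were 1 and 3, and without any one of the other 6 arrays 0 and 0.

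Smad2KO_Smad3het differed from WT in 5017 genes higher and 4055 lower of 13705, a split of 3145 and 4405 with quantile normalization and 3486 and 5813 with centred arrays. Ss18l1 was at least 9.48 higher on the log2 scale, Kbtbd13 at least 9.28, Fam71d at least 8.92, Nrip2 8.91 and Ezr, a linker of membrane and actin, at least 8.87, where the floor of 41.8 sets the bounds and they have no order. Xist, the RNA of the inactive X chromosome, was at -6.05 (adjusted p = 0.000103), Nsd3 at -4.55 or lower, Kdm6b, a histone demethylase gene, at -4.16 or lower, Nup54 at -3.77 and Atp1b1 at -3.47. Against Smad2KO the counts were 5017 and 4047, 3142 and 4353 with quantile normalization and 3444 and 5788 with centred arrays, with Ss18l1 at 9.48 or higher, Nrip2 at 9.26 or higher, Kbtbd13 at 9.20, Fam71d at 8.92 or higher and Rab38 at 8.92, and with Xist at -6.27, Nsd3 at -4.43 or lower, Kdm6b at -4.13 or lower, Nup54 at -3.91 and Mir1931 at -3.80 or lower. Leaving out the array without or with TGF-b of this genotype gave 2918 or 2857 genes higher than in WT and 2891 or 2886 higher than in Smad2KO. The genotype and whatever sets its 2 arrays apart cannot be told apart in these counts.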

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

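All tests of explanations in this part were chosen after the result was seen, except the comparison of second probe sets between Smad2KO_Smad3het and the other arrays.

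The Smad2KO_Smad3het arrays differed from the other 6 in level, ranks and 9072 called genes. A higher background alone is argued against, because over 8202 bright probe sets their highest rank correlation with any of the other 6 arrays was 0.788, against 0.910 to 0.979 among those 6 and 0.947 with each other, and loss of Smad2, which Smad2KO shares, because only 0.276% of the genes called against WT, 25 of 9072, were at least 2-fold in the same direction in Smad2KO. Changes of single probe sets, as from the array, hybridization or RNA quality, stay open: after quantile normalization, of 2434 genes whose brightest probe set differed at least 2-fold and that had a second, 70.8% had the second differing in the same direction and 12.8% had it 2-fold in the opposite direction, against 0.403% for the WT response to TGF-b. Loss of 1 Smad3 allele as the only difference is argued against, because spiked-in bacterial transcripts, which do not come from the cells, read higher here. Deposited BioB was 758 and 573 against 268 to 382 on the others, and BioDn 4542 and 4402 against 2345 to 2955. How far a difference in processing or the loss of the allele accounts for the called genes cannot be told apart, since both arrays of the genotype and no others carry both. This was not settled.

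Within the same genotype, 2790 genes differed at least 2-fold between cultures with and without TGF-b, more than in any other genotype. Noise of single probe sets on these 2 arrays is a candidate explanation: over genes whose brightest probe set differed at least 2-fold within the pair, 45% of 864 second probe sets differed in the same direction, against 83.1%, 88.1% and 92.6% in WT, Smad2KO and Smad3KO. A response of this genotype to TGF-b may lie among these genes, but it was not separated from the noise.

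TGF-b responses were smaller in Smad3KO than in WT and Smad2KO. A compressed signal range of the Smad3KO arrays is argued against, because the log2 ratio of their 98th percentile to the median was 7.05 or more, above the 6.81 and 6.90 of WT. One common factor for all responses, as from a weaker stimulus, stays open: with a factor of 0.531 on the Smad2KO picks, 8.33% of genes (27 of 324, 12 larger and 15 smaller) lay beyond 4 noise SDs, against 0.158% of all bright genes, and this noise may be underestimated for genes picked by size. Loss of Smad3 may account for the median of 0.785 in Smad3KO over the genes picked in Smad2KO, but with 1 pair of cultures it cannot be told apart from a difference between cultures.

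The mean response was set against other divisions of the arrays. On 8 arrays the real division into with and without TGF-b called 19 genes, and of 32 divisions that could be fitted (3 of 35 could not) it was the only 1 to call as many, with 0 in the highest other. Only 8 of the 32 part the 2 arrays of every genotype as the real one does, which is too few for a share under 0.05. On 6 arrays the real division called 1211 genes and the highest other 0, and the 10 divisions, 4 of them of that kind, are too few as well.

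Some single results stood out and are given as values. Cnpy2 went opposite ways with TGF-b in 2 genotypes, at 2.25 or more on the log2 scale in WT and -1.83 or lower in Smad2KO, and Samhd1 at -1.08 in Smad2KO and 1.67 in Smad3KO. The difference between the 2 genotypes was not tested for either gene, no test of responses on the 8 arrays called them, the tests on the 6 read other probe sets of these genes, they were 1 of 253 and 1 of 122 genes at 2-fold in both genotypes compared, and other probe sets did not show it: a second for Cnpy2 read 1184 and 1540.3 in WT and 1151 and 1485 in Smad2KO, and a second for Samhd1 636 and 1197 in Smad2KO and 835 and 953 in Smad3KO. Tatdn2, called for Smad2 dependence at 1.68 on the 6 arrays, read 134 in Smad2KO with TGF-b and 327 to 538 on the other 5. AY036118, called for WT against the mutants at 3.13, read 198 in WT without TGF-b and 1059.6 to 1754 on the others, and the 3 probe sets for 18S ribosomal RNA read 3424, 2680.2 and 2226 on that array and 777, 2166 and 747 in Smad3KO without TGF-b, where AY036118 read 1754. Of 1323 probe sets unnamed here and bright enough, 20 were at least 2-fold higher with TGF-b in WT, Smad2KO and Smad3KO alike and 1 was lower, the largest at 3.33, 3.03 and 2.44 in the 3 genotypes.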

How the results depend on the processing

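The floors at each array's own median and at the 75th percentile, and the settings without both Smad2KO_Smad3het arrays, were chosen after seeing the data; the others were planned. No response of 2-fold or more of the genes named in WT, Smad2KO and Smad3KO changed sign. Of 39 named genes with a mean response on 8 and on 6 arrays, 4 differed in sign: Itgb5 at 0.49 and -0.68, Rpl41 at -1.01 and 0.16, Rab6b at -1.13 and 0.24, and Tbx21 at 0.02 and -0.16. The balance of higher and lower turned for 3 counts. Smad2KO_Smad3het had more genes higher than lower, and had more lower with quantile normalization (3145 and 4405 against WT, 3142 and 4353 against Smad2KO), centred arrays (3486 and 5813, 3444 and 5788), a filter on mean signal (3999 and 4086, 3994 and 4082) or without either of its arrays. With a floor at the 25th percentile, Smad2KO had more genes 2-fold lower with TGF-b than higher, and fewer higher than Smad3KO. All 99 values of named genes were within 1.5-fold with centring, quantile normalization, no filter or a filter on the mean, 86 with each array's own floor, 77 with a floor at the 25th percentile or none, 75 with the mean of probe sets and 75 on the 6 arrays, but only 29 of 72 with a floor at the 75th percentile. Signal over background limits the 2-fold counts: with a floor at the 25th percentile they grew in every genotype, and the median signals of the Smad2KO_Smad3het arrays, 88.0 and 90.9, lay above the floor of 41.8. Except where the change itself means fewer arrays, other floors or other genes tested, the cause was not tested.

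With quantile normalization the median responses of WT picks were 0.908 in Smad2KO, 0.586 in Smad3KO and 0.271 in Smad2KO_Smad3het, 70 genes rose and 28 fell in the mean response, Smad2KO against WT gave 3 higher and 2 lower, Smad3KO against WT 3 lower, Smad2KO_Smad3het 3145 higher against WT and 3142 against Smad2KO, and 1 list was called for Smad2 dependence. With centred arrays 11 genes fell in the mean response and 0 were lower in Smad3KO.

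With the floor at the 25th percentile, genes at 2-fold higher and lower with TGF-b numbered 1195 and 1172 in WT, 668 and 849 in Smad2KO, 711 and 593 in Smad3KO and 2430 and 2139 in Smad2KO_Smad3het. The medians of WT picks were then 0.196, 0.0944 and 0.0876 in Smad2KO, Smad3KO and Smad2KO_Smad3het, those of Smad3KO picks 0.182 in WT and 0.123 in Smad2KO, and those of Smad2KO picks 0.423 in WT and 0.177 in Smad3KO. The mean response gave 61 and 23 genes, Smad2KO against WT 3 and 3, Smad3KO 3 lower, and lists 1 for WT against the mutants and 0 for Smad2 dependence. With no floor the WT picks had 1.06 in Smad2KO and 0.741 in Smad3KO, the mean response gave 173 and 85 genes, Smad2KO 6 and 7, Smad3KO 3 lower, and both differences between responses 0 lists.

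With the floor at each array's own median, Smad2KO_Smad3het had 728 genes higher and 606 lower, WT picks 0.157 in that genotype and Smad2KO picks 1.33 in WT. With the floor at the 75th percentile the counts were 144 and 63 in WT, 89 and 35 in Smad2KO, 51 and 18 in Smad3KO and 304 and 235 in Smad2KO_Smad3het, Smad3KO picks had 1.87 in WT, Smad2KO picks 0.879 in Smad3KO, and the mean response gave 103 and 59 genes.

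With no filter on dim probe sets the mean response gave 1 and 0 genes, Smad3KO 0 lower and Smad2 dependence 2 lists. With a filter on mean signal Smad2KO_Smad3het had 885 genes higher and 767 lower, the mean response gave 58 and 22 and Smad3KO 2 lower. With the mean of all tested probe sets the mean response gave 8 higher, and Smad2KO against WT 6 and 2. With limma's eBayes without trend and robust settings the mean response gave 0 and 0 and Smad3KO 0 lower. With no replicate block, so with genotype left out of the model, the mean response gave 5 and 0 genes. Picking genes at 3-fold gave medians of 1.53, 1.03 and 0.679 for WT picks in Smad2KO, Smad3KO and Smad2KO_Smad3het, 2.52 and 2.10 for Smad3KO picks in WT and Smad2KO and 2.35 and 1.47 for Smad2KO picks in WT and Smad3KO, larger by construction. Camera with an estimated correlation called 0 lists for the mean response, 0 for WT against the mutants and 0 for Smad2 dependence. As said above, this setting was weaker by itself with these few arrays.

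Without both Smad2KO_Smad3het arrays WT picks had 0.892 in Smad2KO and 0.599 in Smad3KO, Smad2KO against WT gave 49 and 47 genes, Smad3KO 21 and 23, and WT against the mutants 2 lists. Without them the mean response gave 645 and 550 genes with quantile normalization and 646 and 602 with centred arrays. Leaving out 1 pair at a time gave 0 to 677 genes higher and 0 to 534 lower in the mean response, the highest without the Smad2KO_Smad3het pair. It gave 0 to 2 higher and 0 to 3 lower for WT against the mutants, and 1 to 478 higher and 0 to 398 lower for Smad2 dependence, the highest without the Smad2KO pair. Leaving out 1 array at a time gave 0 to 8 higher and 0 to 13 lower in Smad2KO, 0 to 1 higher and 0 to 3 lower in Smad3KO, and, for genes higher in Smad2KO_Smad3het, 2857 to 4408 against WT and 2886 to 4502 against Smad2KO. A left-out array leaves its group with 0 samples and its genotype with 1, which is assumed to vary like the others.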

Other observations

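The tests in this part were planned before the values they measure were seen.

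Some responses beyond the named lists differed in size between the genotypes, in genes chosen after their values were seen. H2-DMa, which helps load peptides on MHC class II, was higher with TGF-b by 2.85 on the log2 scale in WT and 2.25 in Smad2KO and stood at -0.20 in Smad3KO. Pdlim5, a scaffold of the actin cytoskeleton, stood at 2.72, 2.19 and -0.08. Tnfsf11, the gene of the osteoclast factor RANKL, was lower, at -1.84, -1.03 and -0.26. Each value is from 1 pair of arrays. On the 6 arrays limma's test of WT against the mutants did not call them (adjusted p = 0.712, 0.697 and 0.546), and Smad3KO against the others was not tested. That test could hardly call them. Its spread on the 6 arrays is the difference between Smad2KO and Smad3KO, by which these genes stood out.

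A hypothesis is that some genes called between a knockout and WT lie near the targeted locus, since a targeted allele can carry along DNA of the cells it was made in, which could alter nearby genes. On the 6 arrays, of the tested genes among the 200 named genes on each side of Smad2, 1 of 126 was called between Smad2KO and WT (Slc12a2 at 0.57), against 1.28 expected (one-sided Fisher's exact p = 0.726). Around Smad3, 3 of 201 were called between Smad3KO and WT (Adpgk at -1.0, Atm at -1.35 and Nt5e at -1.24), against 0.934 expected (one-sided Fisher's exact p = 0.0662). Neither test passed, and with so few calls such a passenger effect may still hold for single genes.

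Xist was low on both Smad2KO_Smad3het arrays, at 53.9 and 83.3 against 3753 to 5328 on the others. A hypothesis is that these cells came from male animals and the others from female ones, which would raise Y-linked genes together. The Y-linked genes tested had a median log2 of the lower Smad2KO_Smad3het signal over the highest other of at least 1.32, above the 0.5 set against this hypothesis. The floor sets this value, since the signals on the other arrays lay under it, so it could not be held against the 2 set in advance for the hypothesis. Eif2s3y read 279 and 214 against at most 12.9 on the others, Kdm5d 131 and 105 against at most 9.21, and Uty 89.5 and 104 against at most 30.6. The labels used here do not give the sex of the animals, and many genes were higher on these arrays, so the hypothesis could not be separated from the other differences of these arrays.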
